A study of Mus musculus with 2 samples.

How the data were processed

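Esophagi were taken from hybrid C57BL/6J and BALB/c mice, stripped of muscle, cut up, digested with trypsin-EDTA and dispersed with a gentleMACS dissociator, per the labels' protocols. Single-cell libraries were made with the 10x Genomics Chromium Next GEM 3′ chemistry, which captures polyadenylated RNA and tags each molecule with a UMI, per the labels' protocols. Cell Ranger 6.0.1, R 4.1.1, Seurat 4.0.2 and the mm10 genome build are named in the submitters' processing notes, which give no parameters here. The gene annotation used for counting, the exons deleted from the floxB allele, and the time after Cre induction are not given in the sources used here.

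The deposited table holds natural log values, which the authors made by scaling each cell to 10000 and adding 1 before the logarithm, as read from the values themselves: the exponential minus 1 summed to 10000 in each of the 4853 cells. The smallest step of each cell then gave back its UMI counts, and 100% of the positive values came out whole within 0.01 UMIs. The counts recovered in this way were used for all sums, and the plan for counts was followed. A deposited table of the authors gives each cell's library, its cell type and 1 of 19 cluster numbers; these labels were used as given. The table holds 18595 genes, of which 268 were seen in under 3 cells. Cells had between 500 and 100520 UMIs, at least 201 genes and at most 5.00% mitochondrial UMIs, which shows the filters that the deposited cells had passed. No cell was removed for the main values. Gene locations come from the GENCODE mouse annotation on mm10 (vM21), in which 18323 of the 18595 names (98.5%) were found.

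Cell types were checked against 21 fixed marker lists, among them lists for other tissues that the sample could hold. A class was compared by name when no cluster of it had more markers of another class than of its own among its 10 leading genes by fold. Clusters 6 and 12 lost their names by this rule and by depth, and cluster 16 mixed cycling keratinocytes with cycling T cells, so fibroblasts, T cells and the cells annotated as B cells were compared by cluster number. Cluster 6 held 185 and 115 cells and cluster 16 held 24 and 48, and neither entered a comparison of expression, except that keratinocytes and dendritic cells or macrophages of cluster 16, called by markers, were added in alternatives. Doublets were called with Scrublet, which marked 17 of 2472 control cells (0.688%) and 2 of 2381 Keap1 cKO cells (0.0840%); so few marked cells mean that doublets were in effect not removed.

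UMIs were summed over the cells of a class or cluster in each library and given as counts per 1000000 (CPM). Single sums carry exact Poisson intervals, ratios exact conditional binomial intervals, and shares of cells exact Clopper-Pearson intervals, all at 95%. A gene with 0 UMIs in 1 library was set to a floor of 3 counts over the group and is given as a lower bound. This bound is the ratio at that floor and not the end of an interval. The exact 95% interval reaches smaller folds, for Reg3g in epithelial cells 8209 against 10096. List medians and gene ratios of a class or cluster were given only with at least 50 cells per library. The NRF2 share per cell in cluster 14 (42 and 40 cells) and the cells of cluster 4 above the control 95th percentile (14 cells) are exceptions. The 25 gene lists, 7 of them for NRF2, the named-gene rule and a first set of alternatives were fixed before the data were examined; other alternatives were added after the data were seen. A list's value is the median log2 ratio over members with at least 20 UMIs over both libraries. Its counting interval comes from 1000 resamples of the counts, and its percentile from 10000 random lists matched on expression in 20 bins. In the resamples a 0 was set to 1 count and not to 3. The interval of a list with members at 0 can therefore lie off its median. Members at least 1.5-fold apart are counted to describe a list and are not calls. For shares of cells with a UMI, each cell was thinned to 1 depth and shallower cells were left out.

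Genes were named by a fixed rule. In epithelial cells the rule took the 12 highest and 12 lowest log2 ratios among genes with at least 100 UMIs over both libraries and at least 50 CPM in 1 of them, with the same direction in every epithelial cluster with at least 50 cells per library and at least 20 UMIs of the gene. It took 3 per direction in each other class or cluster, the 2 most abundant and the 2 most different members of each list, and always Keap1, Nqo1, Gclc, Gclm, Txnrd1, Slc7a11, Krt5 and Krt14. Inmt in cluster 1 and Ccl5 in cluster 11 met the rule but are defining genes of those clusters and are not given as results; a few other ranked genes of the smaller classes are left out for length. Krt6a, Krt6b, Krt16, Krt17, Srxn1, Prdx1 and Nfe2l2, where outside the rule, were chosen after their values were seen. Mitochondrial genes, hemoglobins, receptor segments and sex-linked genes were kept out of the ranking.

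The alternatives were other cell filters, keratinocytes called by markers, the mean over cells, equal weights for clusters, median-of-ratios scaling, other minimums for list members, removal of Scrublet-marked cells, other thinning depths and other totals. Equal weights took the mean of the log2 ratios of clusters 4, 9, 10 and 13, without clusters 14 and 15. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9, with random seed 1. The steps were tested on simulated counts for the epithelial comparison over 12638 genes. There, 95.8% of intervals held the true ratio. The simulated counts were drawn gene by gene from the Poisson model that the intervals assume. They therefore check the calculation, and not the spread between cells or animals or genes that vary together. Of 100 unchanged lists, 7% lay outside the 2.5 to 97.5 percentile. The sign was right for 98% of genes with a simulated fold of 0.5 and for 100% at folds of 1.5, 2.0 and 4.0.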

Results

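Single cells from the esophagus of mice, taken after the muscle layer had been removed, were profiled with droplet 3′ RNA sequencing. One library came from a control mouse genotype, in which both copies of Keap1 carry the floxB allele. The other came from the same floxed genotype with K5CreERT2, a tamoxifen-inducible Cre recombinase under the keratin 5 promoter, and is called the Keap1 cKO library here. Keap1 encodes the adaptor that marks the transcription factor NRF2 (gene Nfe2l2) for degradation. The control library held 2472 cells and 30501227 unique molecular identifiers (UMIs), with a median of 11293.5 UMIs and 3292 genes per cell. The Keap1 cKO library held 2381 cells and 26036522 UMIs, with a median of 8193 UMIs and 2630 genes per cell. With 1 library per genotype there were no replicates, so no test was made, and all intervals are 95% intervals that cover counting error only. They are exact except those of list medians, which come from resampled counts. Epithelial values were summed over all cells the authors annotated as epithelial, 848 in the control library and 422 in the Keap1 cKO library. Cluster 4 held more of these cells than any other cluster in the control library (313), and cluster 9 did so in the Keap1 cKO library (140). The median depth of epithelial cells was 17667 UMIs in the control library and 5072.5 UMIs in the Keap1 cKO library.

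The first comparison concerns which cell classes were recovered from each genotype. Epithelial cells made up 34.3% (32.4 to 36.2) of the control library and 17.7% (16.2 to 19.3) of the Keap1 cKO library, a 1.94-fold lower share. Fibroblasts of cluster 1 made up 22.0% (20.4 to 23.7) and 7.85% (6.80 to 9.01), and those of cluster 5 made up 10.96% (9.76 to 12.3) and 5.29% (4.43 to 6.27). Immune and endothelial cells took larger shares of the Keap1 cKO library. Myeloid cells made up 6.998% (6.02 to 8.08) of the control library and 17.3% (15.8 to 18.9) of the Keap1 cKO library, and endothelial cells 3.24% (2.57 to 4.01) and 9.16% (8.03 to 10.4). T cells called by fixed markers such as Cd3e, a subunit of the T cell receptor complex, made up 4.21% of the control library and 23.3% of the Keap1 cKO library. Most of them lay in cluster 3, a T cell cluster led by Cd163l1, Il17a, Trdv4 and Trdc, which held 59 cells or 2.39% (1.82 to 3.07) of the control library and 378 cells or 15.9% (14.4 to 17.4) of the Keap1 cKO library. Il17a and Ccl5, defining genes of the T cell clusters 3 and 11, differed between the libraries, so the sizes of these clusters are given as composition. Leading genes were read over both libraries together, and cluster 3 held 320202 control and 3218498 Keap1 cKO UMIs. Its leading genes may therefore not describe its 59 control cells. Cluster 11 held 58 and 163 cells, 2.35% (1.79 to 3.02) and 6.85% (5.86 to 7.94). Cluster 12 held 34 and 178 cells, 1.38% (0.954 to 1.92) and 7.48% (6.45 to 8.61). The authors annotated cluster 12 as B cells, but its leading genes included Cd207, the Langerhans cell lectin langerin, Ccr7 and the class II gene H2-Eb1. Dendritic or Langerhans markers outnumbered those of other types in 22 of its 34 control cells and 125 of its 178 Keap1 cKO cells. Cluster 17, led by the neutrophil genes Retnlg, Csf3r and Cxcr2, held 4 and 56 cells. Erythrocytes made up 7.20% (6.21 to 8.29) and 5.04% (4.20 to 6.00), and myocytes 0.688% and 0.588%. Every cell in the table had at least 500 UMIs, so these shares can move with the depth gap between the libraries and with the yield of each class at dissociation.

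**Figure D1:**
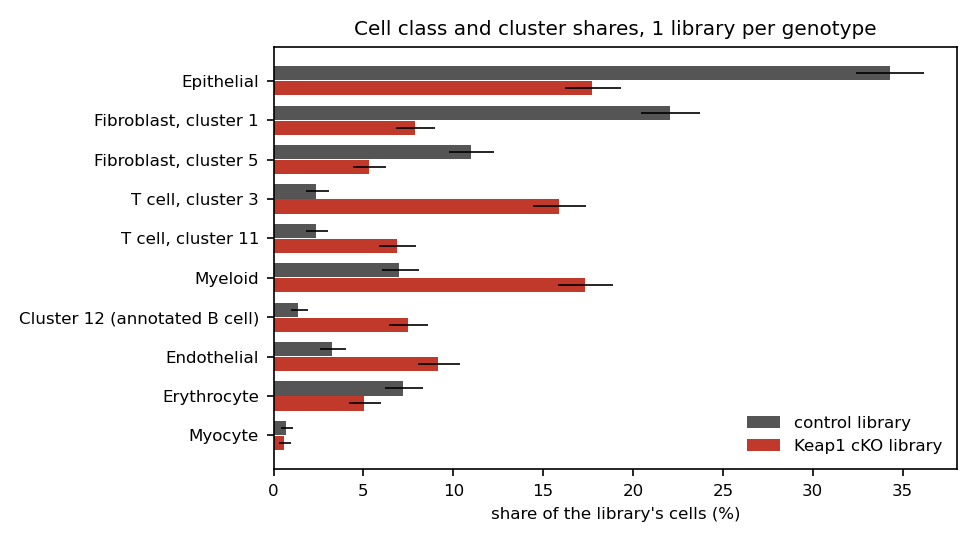
Percent of the cells of each library (horizontal axis) in each annotated class or cluster, with exact 95% binomial intervals for counting error. Epithelial cells lie at 34.3% in the control library and 17.7% in the Keap1 cKO library, and the T cell cluster 3 lies at 2.39% and 15.9%.

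Keap1 itself (mm10 chromosome 9, 21229730 to 21239361, minus strand, protein coding) was lower in the epithelial cells of the Keap1 cKO library. It had 961 UMIs in the control library, 69.8 counts per 1000000 (CPM), and 332 UMIs or 44.5 CPM in the Keap1 cKO library, a log2 ratio of −0.65 (−0.83 to −0.47), or 1.57-fold lower. Keap1 was 1.32-fold lower in cluster 4, where the log2 ratio was −0.40 (−0.67 to −0.13). In the suprabasal cluster 13 it was −0.62 (−0.98 to −0.28), and in the cornified cluster 9, with 20 and 10 UMIs, it was −2.14 (−3.40 to −0.98). Outside the epithelial class, Keap1 had 832 and 829 UMIs and a log2 ratio of −0.16 (−0.30 to −0.02). It was −0.04 in fibroblast cluster 1, −0.48 (−0.84 to −0.13) in fibroblast cluster 5 and −1.11 (−1.71 to −0.47) in T cell cluster 3, although keratin 5 is not a gene of fibroblasts or T cells. Keap1 reached 0.0225 UMIs per red blood cell in the control library and 0.0167 in the Keap1 cKO library, against 1.13 and 0.787 per epithelial cell. After each epithelial cell was thinned to 700 UMIs, Keap1 was seen in 33 of 771 control cells, 4.28% (2.96 to 5.96), and in 2 of 385 Keap1 cKO cells, 0.519% (0.0630 to 1.86); 77 and 37 shallower cells were left out. At full depth the shares were 53.5% and 32.7%. No class here can be taken to lack Keap1, and the T cell cluster 3, thinned to 3900 UMIs, had shares of 26.4% and 18.2%. The exons that the floxB allele loses are not given in the sources used here, so a 3′ tag may lie outside the deleted part and Keap1 UMIs may not measure deletion. Averaged over cells instead of summed, the Keap1 log2 ratio was −1.14. Nfe2l2, which encodes NRF2, had a log2 ratio of 0.07 (−0.01 to 0.15).

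The next question was whether genes that NRF2 is known to activate differed in epithelial cells. They were higher as a group in the Keap1 cKO library: the median log2 ratio over the 70 measured members of 7 fixed NRF2 lists was 0.62 (0.58 to 0.68), and 38 members were at least 1.5-fold higher against 3 that were at least 1.5-fold lower. As a description of these libraries, this median lay above all 10000 random lists matched on expression. Genes of glutathione synthesis and cystine uptake had the highest list median, 1.498 (1.35 to 1.64; percentile 99.99), with 6 of 7 members at least 1.5-fold higher. Slc7a11, the cystine importer (chromosome 3, 49892526 to 50443614), had 22 UMIs or 1.60 CPM in the control library and 817 UMIs or 109.6 CPM in the Keap1 cKO library, a log2 ratio of 6.10 (5.49 to 6.78). The catalytic subunit of glutamate-cysteine ligase, Gclc (chromosome 9, 77754535 to 77794485), stood at 42.5 and 396.8 CPM, a log2 ratio of 3.22 (3.09 to 3.35). The modifier subunit, Gclm (chromosome 3, 122245557 to 122270732), stood at 298 and 624 CPM, 1.07 (1.004 to 1.13). Quinone, aldehyde and carbonyl detoxification genes had a median of 0.72 (0.65 to 0.78; percentile 100), with 10 of 18 members at least 1.5-fold higher and 1 lower. In this list the quinone reductase Nqo1 (chromosome 8, 107388225 to 107403206) stood at 90.7 and 162 CPM, 0.84 (0.73 to 0.96), the aldo-keto reductases Akr1b8 and Akr1c13 at log2 ratios of 2.28 and 2.01, Adh7 at 0.36 and Esd at 1.16.

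Glutathione S-transferases had a median log2 ratio of 0.67 (0.60 to 0.69; percentile 99.99) in epithelial cells, with 10 of 16 members at least 1.5-fold higher and 2 lower. Gsta1 was 3.64 and Gstm3 2.24, while the abundant Gsta4 and Gsto1 were 0.61 and 0.71. Close relatives of the Gsta and Gstm families can share reads, so single members are less certain than the list. Genes of NADPH supply and the pentose phosphate pathway had a median of 0.91 (0.82 to 0.97; percentile 99.88; 4 of 6 at least 1.5-fold higher), with malic enzyme Me1 at 1.42, Idh1 at 1.13, Taldo1 at 0.75 and transketolase Tkt at −0.50. Thioredoxin and peroxiredoxin genes had a median of 0.84 (0.80 to 0.89; percentile 99.92; 4 of 7), with sulfiredoxin Srxn1 at 3.91 (3.66 to 4.18), Prdx1 at 1.90, Txn1 at 0.32 and thioredoxin reductase Txnrd1 (chromosome 10, 82833951 to 82897712) at 1.17 (0.99 to 1.35), at 33.3 and 75.01 CPM. The heme and iron list, 0.27 (0.24 to 0.49; percentile 92.06; 3 of 7), and the efflux and signalling list, 0.12 (0.04 to 0.27; percentile 82.98; 1 of 11 higher and 1 lower), lay inside the central 95% of random lists. Within them, heme oxygenase Hmox1 had a log2 ratio of 3.12 (2.77 to 3.47) and Blvrb 1.98, and the ferritin genes Fth1 and Ftl1 had 0.03 and 0.27. Abcc4 and Pir, of the efflux and signalling list, stood at 0.61 and 0.04. That list also holds Nfe2l2 and the targeted gene Keap1, which is its 1 lower member. Both genes were left out of the joint NRF2 lists and of the NRF2 share per cell. In cluster 4 alone the heme and iron list lay above the central 95% of random lists, at 0.85 (0.40 to 1.13, percentile 99.83). The efflux and signalling list stayed inside that range there, at 0.23 (0.09 to 0.38, percentile 87.33).

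The NRF2 lists differed between epithelial clusters. Their joint median log2 ratio was 0.80 (0.65 to 0.84) in cluster 4, with 39 of 67 members at least 1.5-fold higher and 4 lower, and 1.14 (1.07 to 1.49) in cluster 9, with 42 of 63 higher and 6 lower. In cluster 13 it was −0.21 (−0.32 to −0.10), with 14 of 68 members at least 1.5-fold higher and 23 lower. In cluster 10 it was −0.60 (−0.84 to −0.35), with 1 of 35 members at least 1.5-fold higher and 18 lower. Cluster 10 held 170 and 81 cells at median depths of 1178 and 809 UMIs, and erythroid markers outnumbered those of other types in 109 and 30 of them. Nqo1 had log2 ratios of 0.62 in cluster 4, −1.01 in cluster 13 and 3.28 in cluster 9. In cluster 13 the glutathione S-transferase list was −0.63 and the detoxification list −0.59, whereas glutathione synthesis and cystine uptake was 0.96. With clusters 4, 9, 10 and 13 weighted equally, the detoxification list turned to −0.17. Outside the epithelium, the joint NRF2 median was −0.23 (percentile 2.0) in fibroblast cluster 1, −0.33 (percentile 0.14) in fibroblast cluster 5, 0.07 in myeloid cluster 2, 0.20 in T cell cluster 3, 0.30 in T cell cluster 11 and 0.10 in endothelial cluster 8. In cluster 8 it was −0.025 with median-of-ratios scaling. That scaling moved all genes by 0.10 on the log2 scale in cluster 5, −0.11 in cluster 11 and −0.13 in cluster 8, and by 0.04 in epithelial cells.

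**Figure D2:**
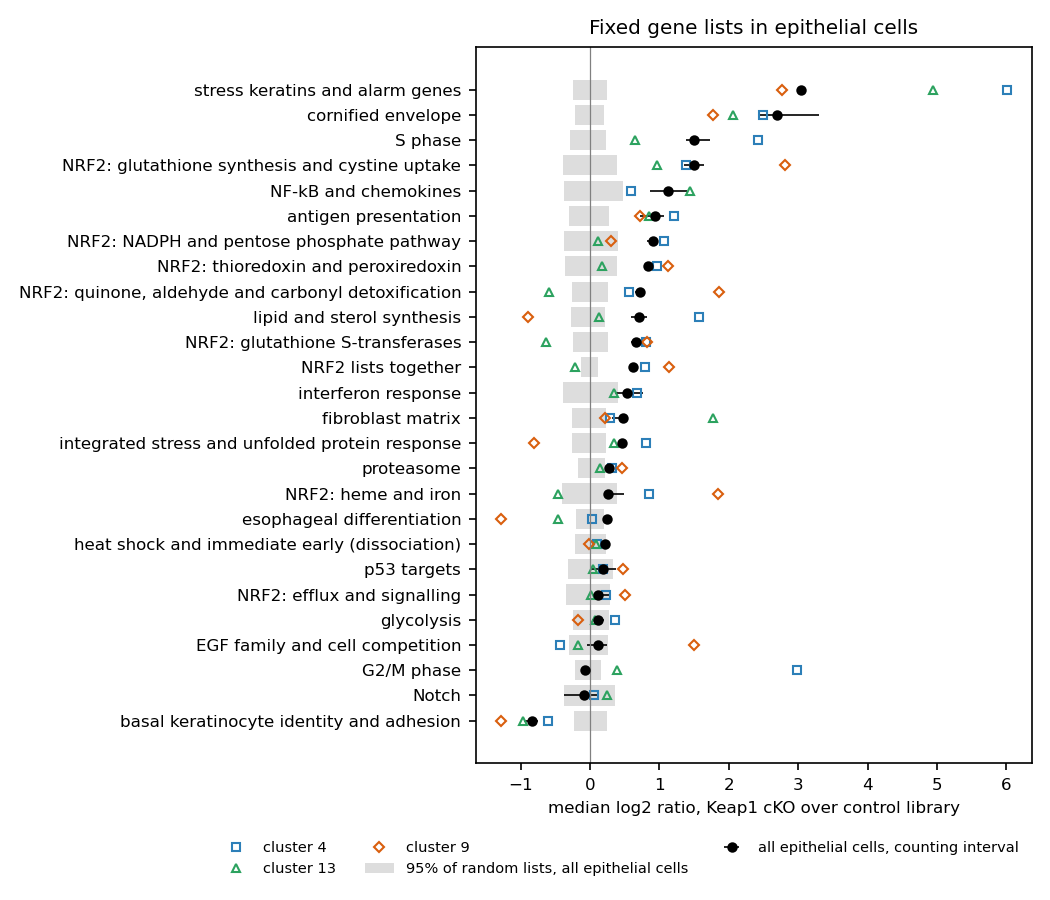
Median log2 ratio of CPM, Keap1 cKO over control library (horizontal axis), for each fixed gene list in all epithelial cells (black, with 95% counting interval) and in clusters 4, 9 and 13 (open symbols), over the central 95% of matched random lists (grey). The stress keratin and alarm list has the highest epithelial median, 3.04, and the basal identity list the lowest, −0.83.

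Because Cre recombination can be mosaic, the percent of each cell's UMIs that came from the NRF2 lists was compared cell by cell. The median epithelial cell gave 1.58% in the control library and 1.48% in the Keap1 cKO library, but the 90th percentile was 2.83% and 11.3%. The 95th percentile of control epithelial cells, 4.08%, was exceeded by 43 of 848 control cells (5.07%) and 101 of 422 Keap1 cKO cells, 23.9% (19.9 to 28.3). Of the 43 control cells 37 lay in cluster 14, while of the 101 Keap1 cKO cells 72 lay in cluster 9, 12 in cluster 4 and 11 in cluster 14. The medians were 7.41% and 2.78% in cluster 14, and 1.60% and 1.03% in cluster 10. This threshold marks a range and not a cell type; 27 control and 13 Keap1 cKO cells lay within 20% of it. In cluster 9, 72 of 140 Keap1 cKO cells, 51.4% (42.8 to 60.0), exceeded that cluster's own control 95th percentile of 3.75%, and 27 control and 2 Keap1 cKO cells lay within 20% of it. In cluster 4, 13 of 93 Keap1 cKO cells, 13.98% (7.66 to 22.7), exceeded 1.94%, with 80 control and 13 Keap1 cKO cells near it. In cluster 13, 3 of 61 Keap1 cKO cells, 4.92% (1.03 to 13.7), exceeded their threshold against 7 of 134 control cells. When Fth1 and Ftl1 were left out, an alternative chosen after the data were seen, the direction of the epithelial medians turned, to 1.18% in the control library and 1.25% in the Keap1 cKO library. After thinning to 700 UMIs, Slc7a11 was seen in 0.519% of control and 3.64% of Keap1 cKO epithelial cells, and at full depth in 2.24% and 24.2%. T cells of cluster 3, at median depths of 5299 and 8224.5 UMIs, had an Slc7a11 UMI in 0 of 59 cells, where 3 counts, taken as the limit, would be a share of 5.08% of cells with a UMI, and in 3.17% of 378 cells.

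**Figure D3:**
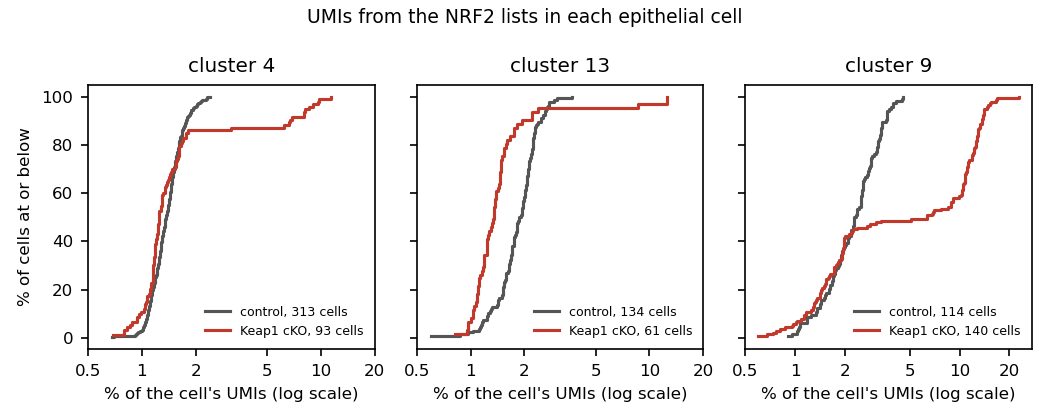
Cumulative percent of cells (vertical axis) at or below a given percent of the cell's UMIs from the NRF2 lists (horizontal axis, log scale), for control and Keap1 cKO cells of clusters 4, 13 and 9. The Keap1 cKO curve of cluster 9 has a long upper part, with 51.4% of its cells above the control library's 95th percentile of 3.75%, and that of cluster 4 a shorter one, with 13.98% of its cells above 1.94%.

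Genes were then named by the size of their ratio among 1113 epithelial genes with enough UMIs. The highest ranked genes included several that encode secreted mucosal proteins, alarm proteins and proteins of the cornified envelope. Reg3g, an antibacterial lectin (chromosome 6, 78466269 to 78468872), had 0 UMIs in the control library and 16397 in the Keap1 cKO library, at least 10096-fold higher against a floor of 3 counts over the group. Of these UMIs 15951 came from cluster 14, of which Reg3g is a defining gene, and with that cluster left out the log2 bound was 8.25. Muc5b, a secreted mucin, and Itln1, an intelectin, also had 0 control UMIs, with 1866 and 731 in the Keap1 cKO library, at least 1149-fold and 450.1-fold higher, of which 1848 and 726 lay in cluster 14. Tff2, a trefoil peptide of mucous cells, had 2 and 1413 UMIs, a log2 ratio of 10.35 (8.49 to 13.40), with 1402 in cluster 14. Fixed markers of gastric and airway epithelium stood at 1082 and 419 CPM in cluster 14 over both libraries, and at no more than 42.2 and 14.1 CPM in any other epithelial cluster. Tff2 is itself one of the gastric markers, so that value is not separate from it. By their leading markers, 42 of 42 control and 39 of 40 Keap1 cKO cells of cluster 14 were called keratinocytes. S100a8 and S100a9, subunits of calprotectin, had log2 ratios of 9.29 (9.08 to 9.52) and 8.70 (8.48 to 8.92); S100a8 (chromosome 3, 90668978 to 90670035) had 169 and 57468 UMIs. The acute phase gene Saa3 stood at 9.37 (7.82 to 11.65), from 3 to 1073 UMIs, and the siderophore-binding lipocalin Lcn2 at 7.62 (6.77 to 8.62). Of cornified envelope genes, Sprr2h had 1 and 676 UMIs, 10.29 (7.80 to 15.59), Sprr2e 0 and 1025, at least 631-fold higher, and Lce3d 0 and 654, at least 403-fold higher; 988 of the Sprr2e UMIs and 647 of the Lce3d UMIs came from cluster 9, of which Sprr2e is a defining gene. Uox, urate oxidase, had 0 and 391 UMIs, at least 241-fold higher.

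The lowest ranked gene was Ndufa4l2, which encodes a mitochondrial protein induced by hypoxia (chromosome 10, 127514967 to 127517154). It had 5023 and 106 UMIs, a log2 ratio of −4.68 (−4.97 to −4.40). Il1r2, the decoy receptor for interleukin 1, was −3.31, the keratin Krt32 −3.27, the prolyl hydroxylase Egln3 −3.17, the apolipoprotein Apoe −3.12 and the Notch ligand homologue Dlk2 −3.01. Dapl1, Rgcc, Ahnak2, Retnla, Sox15 and Efemp1 followed, between −2.70 and −2.24. Free RNA was read from red blood cells. S100a8 reached 1.03 UMIs per red cell in the Keap1 cKO library against 136 per epithelial cell, and Reg3g 0.300 against 38.9. Retnla in the control library reached 0.792 UMIs per red cell against 1.57 per epithelial cell. After thinning to 700 UMIs, S100a8 was seen in 0.778% of control and 71.4% of Keap1 cKO epithelial cells, and at full depth in 1.77% and 90.3%. At full depth S100a8 was also seen in 74.3% of the T cells of cluster 3 in the Keap1 cKO library and in 0 of 59 in the control library, where 3 counts would be 5.08%.

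**Figure D4:**
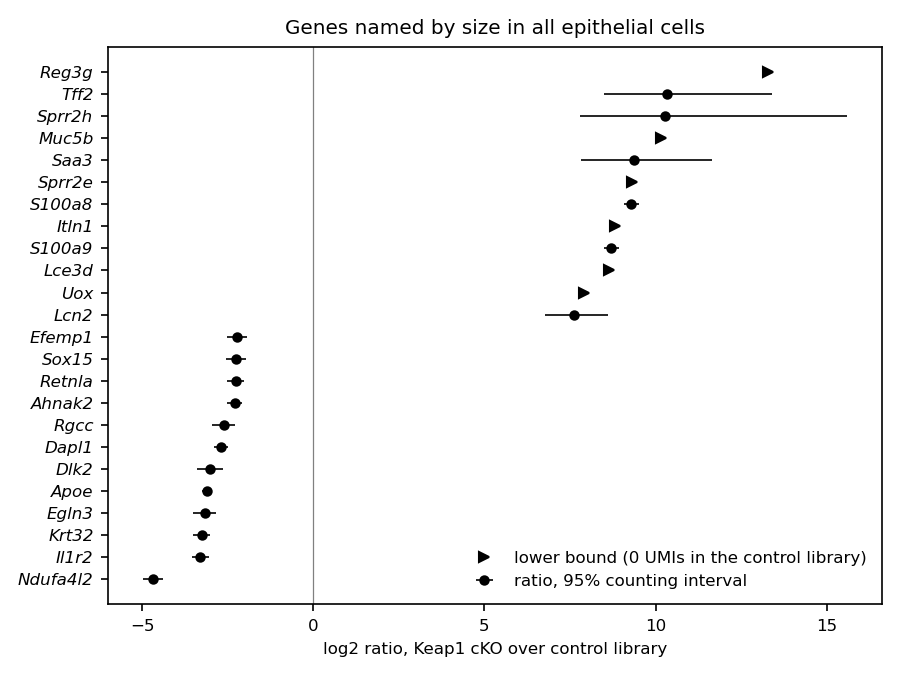
Log2 ratio of CPM, Keap1 cKO over control library, for the 12 highest and 12 lowest ranked epithelial genes, with exact 95% counting intervals; genes with 0 control UMIs are drawn at their lower bound. Reg3g stands highest and Ndufa4l2 lowest, at −4.68.

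Keratinocyte state genes were compared through 4 fixed lists. Basal identity and adhesion genes were lower in the Keap1 cKO library, with a median log2 ratio of −0.83 (−0.95 to −0.76), below all random lists, and 11 of 16 members at least 1.5-fold lower against 1 higher. Krt15, a keratin of basal cells, had 82787 and 14267 UMIs, −1.65, and the hemidesmosomal collagen Col17a1 −1.72. The basal keratins Krt5 (chromosome 15, 101707070 to 101712898) and Krt14 (chromosome 11, 100203162 to 100207548) moved apart, at −0.01 (−0.03 to 0.01) and 1.15. Stress keratins and alarm genes had a median of 3.04 (3.003 to 3.09; percentile 100), with 13 of 16 members at least 1.5-fold higher and none lower. Within that list, Krt6a stood at 2.77, Krt6b at 5.32, Krt16 at 7.46, Krt17 at 3.82 and the fatty acid binding protein Fabp5 at 2.02. The same list had medians of 3.51 in red blood cells and 4.60 in fibroblast cluster 1, which are not keratinocytes. Cornified envelope genes had a median of 2.70 (2.44 to 3.29; percentile 100), with 23 of 25 members at least 1.5-fold higher and 1 lower; Crct1 was 1.98 and Sprr1a 2.43. Esophageal differentiation genes had a median of 0.25 (0.20 to 0.29; percentile 99.07), with 9 of 22 members higher and 4 lower. The suprabasal keratins Krt13 and Krt4 were −0.79 and −0.67, Cnfn 1.56 and the transcription factor Grhl1 1.34. The direction of this list rested on pooling, since it was 0.026 in cluster 4, −0.46 in cluster 13 and −1.28 in cluster 9. With clusters 4, 9, 10 and 13 weighted equally the list was at −0.43. The other three lists kept their direction in clusters 4, 9 and 13. In cluster 10 stress keratins and alarm genes stood at 2.73, but basal identity at 0.12 (−0.18 to 0.42), with 3 of 13 members higher and 2 lower.

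Cell cycle genes were compared in the same way. S phase genes were higher in the epithelial cells of the Keap1 cKO library, with a median log2 ratio of 1.504 (1.38 to 1.72; percentile 100), 24 of 25 members at least 1.5-fold higher and 1 lower. The ribonucleotide reductase subunit Rrm2 stood at 3.45, the exonuclease Exo1 at 3.40, the nucleotide hydrolase Dut at 0.61 and Cdca7 at −0.76. G2/M genes had a median of −0.07 (−0.12 to 0.02; percentile 34.1), with 8 of 28 members at least 1.5-fold higher and 5 lower, among them the kinase Aurkb at 1.75, the kinetochore gene Cenpf at −1.21, Hmgb2 at −0.05 and Tubb4b at −0.08. With clusters 4, 9, 10 and 13 weighted equally, which leaves out the G2/M cluster 15, the G2/M median was 1.93. Within cluster 4 the medians were 2.43 for S phase and 2.98 for G2/M, while cluster 15, defined by G2/M genes, held 75 control cells and 7 Keap1 cKO cells. Cycling keratinocytes were also placed differently by library in cluster 16, led by histone genes and Top2a and annotated as T cells, where markers called 16 of 24 control cells and 0 of 48 Keap1 cKO cells keratinocytes. With these cells added to the epithelial cells, an alternative chosen after the data were seen, the medians were 1.17 for S phase and −0.24 for G2/M. After thinning to 700 UMIs, a UMI of the S phase list was seen in 19.2% (16.5 to 22.2) of control and 26.5% (22.2 to 31.2) of Keap1 cKO epithelial cells, and one of the G2/M list in 53.05% and 51.95%. At full depth the shares were 74.8% and 64.9% for S phase, and 91.0% and 88.2% for G2/M. Fibroblasts of cluster 1, at median depths of 11930 and 14798 UMIs, had S phase UMIs in 87.0% and 84.5% of cells at full depth, so these shares do not single out cycling cells.

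Immune and inflammatory lists were higher in the epithelial cells of the Keap1 cKO library. Antigen presentation genes had a median log2 ratio of 0.94 (0.72 to 1.07; percentile 100; 11 of 15 members at least 1.5-fold higher and 1 lower), with B2m at 1.39, H2-K1 at 1.18, H2-D1 at 0.47 and H2-Eb1 at 1.37. H2-Eb1 reached 0.442 UMIs per red cell in the Keap1 cKO library against 0.675 per epithelial cell. NF-kB targets and chemokines had a median of 1.13 (0.86 to 1.40; percentile 99.97; 11 of 15 higher and 1 lower), with Cxcl3 at 4.43, Il1b at 3.89 (2.17 to 6.26) with 3 and 24 UMIs (0.0333 UMIs per red cell against 0.0569 per epithelial cell in the Keap1 cKO library), Nfkbia at 0.62 and Icam1 at −1.16. Interferon response genes had a median of 0.54 (0.36 to 0.77; percentile 99.35; 6 of 14 higher and 2 lower), with Ifitm3 at 1.56, Oas1a at 2.09, Irf7 at 0.57 and Ifit3 at −2.45. Without cluster 14 the interferon median was 0.18. The T cell genes Cd3e and Il17a had 0.0189 and 0.00825 UMIs per control epithelial cell, and 0.116 and 0.220 per Keap1 cKO epithelial cell. Red cells of the Keap1 cKO library held 0.00833 and 0.0417. Doublets were in effect not removed, so a contribution of immune cells to these lists was not excluded.

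Among stress lists, the integrated stress and unfolded protein response had a median log2 ratio of 0.46 (0.40 to 0.53; percentile 99.95; 5 of 18 members at least 1.5-fold higher and none lower), with Nupr1 at 2.92, the mitochondrial folate enzyme Mthfd2 at 1.87, Hspa5 at 0.41 and Hsp90b1 at 0.10. The proteasome list stood at 0.27 (0.23 to 0.33; percentile 99.52; 2 of 25 higher), with Psmc1 at 0.79, Psma7 at 0.64 and Pomp at 0.36. Heat shock and immediate early genes, which tissue dissociation induces, stood at 0.21 (0.16 to 0.27; percentile 96.4; 3 of 18 higher), with Hspa1b at 0.83, Dusp1 at 0.70, Hspb1 at 0.49 and Hspa8 at 0.11; averaged over cells the median was −0.042. The p53 target list stood at 0.18 (0.02 to 0.38; percentile 88.3; 6 of 17 higher and 1 lower), with Plk2 at 1.36, Sesn1 at −1.49, Cdkn1a at −0.30 and Phlda3 at −0.08. Lipid and sterol synthesis genes had a median of 0.70 (0.59 to 0.82; percentile 100; 8 of 16 higher and 1 lower), with the desaturases Scd1 and Scd2 at 1.60 and 1.47, Fdps at 0.53 and Hmgcs1 at −0.01. That list was 1.57 in cluster 4 and −0.90 in cluster 9. Glycolysis genes had a median of 0.11 (0.02 to 0.21; percentile 79.0; 1 of 15 higher), with Hk2 at 0.60, Pgk1 at 0.50, Pkm at 0.33 and Gapdh at 0.29.

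The Notch and EGF lists lay inside the central 95% of random lists in epithelial cells. Notch pathway genes had a median log2 ratio of −0.09 (−0.38 to 0.11; percentile 35.8; 1 of 9 members at least 1.5-fold higher and 4 lower), with the ligands Dll1 and Jag2 at −1.72 and −1.05, Notch1 at −0.70 and Hes1 at 0.17. When the minimum of 20 UMIs was loosened to at least 1 UMI in each library, which lets in scarcer members, the Notch median was 0.16. The EGF family and cell competition list stood at 0.11 (−0.04 to 0.25; percentile 82.8; 4 of 17 higher and 4 lower). Within it, the EGF receptor ligands Epgn, with 3 and 116 UMIs, and Ereg stood at 6.16 (4.58 to 8.46) and 3.61, Sparc at 0.47 and Wnt4 at −1.20. Fibroblast matrix genes, included as a list of another cell type, had an epithelial median of 0.47 (0.31 to 0.55; percentile 99.95; 8 of 19 higher and 2 lower), with Timp1 at 4.96, Lox at 3.03, Col3a1 at 0.99 and Dcn at −0.98. Col3a1 reached 1.10 and 1.23 UMIs per red cell against 2.35 and 5.08 per epithelial cell, and averaged over cells the list median turned to −0.17.

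Cells outside the epithelium, which do not normally express keratin 5, were compared next. In fibroblasts, matrix genes were higher in the Keap1 cKO library, with a median log2 ratio of 0.91 (percentile 100; 10 of 19 members at least 1.5-fold higher and 2 lower) in cluster 1 and 0.75 in cluster 5. Saa3 had 0 and 1676 UMIs in cluster 1, at least 1299-fold higher, and the adhesion gene Lsamp was lower in cluster 1, at −4.14, and in cluster 5, at −6.32 (−9.37 to −4.45). Ccn5 stood at 6.04 in cluster 5, with 6 and 235 UMIs, and Adh1 and Spock3 at −4.12 and −3.38. In myeloid cells, which pool 169 and 356 cells of cluster 2 with 4 and 56 of the neutrophil cluster 17, the chitinase-like gene Chil3 had 2 and 354 UMIs, 6.93 (5.07 to 9.98), the monocyte gene Ly6c2 1 and 216 UMIs, 7.22 (4.73 to 12.53), and Acod1, a defining gene of cluster 17 that makes itaconate, 0 and 205 UMIs, at least 47.1-fold higher, while Xcl1, with 101 and 1 UMIs, stood at −7.19 (−12.51 to −4.68), Ccl5 at −4.13 and Ryr1 at −3.42. Ccl5 is a defining gene of T cell cluster 11, and Xcl1 had 133 control UMIs there. Doublets were in effect not removed, so a contribution of lymphocytes to Xcl1 and Ccl5 in myeloid cells was not excluded. In T cell cluster 3, Itgb5 had 1 and 266 UMIs, 4.73 (2.24 to 10.04), and Lck, Tnfsf8 and Fyb were −6.93, −4.53 and −4.13. S100a9 and Krt6b stood at 4.60 (2.73 to 7.65) and 4.40 (1.90 to 9.71) there, but reached only 1.29 and 0.561 UMIs per Keap1 cKO cell of cluster 3 against 0.975 and 0.258 per red cell. In T cell cluster 11, Penk had 1 and 221 UMIs, 6.02 (3.53 to 11.33), Il17a, the type 17 cytokine, 2 and 276 UMIs, 5.34 (3.48 to 8.40), and Il1r1 1 and 106 UMIs, 4.96 (2.45 to 10.28), while Xcl1 and Itga1 stood at −3.15 and −2.81. In endothelial cluster 8, where markers called 10 of 203 Keap1 cKO cells and 0 of 53 control cells fibroblasts, matrix genes had a median of 1.24, and Retnla, Serpina3n and Depp1 stood at −4.43, −3.77 and −3.76. The lymphocyte genes Icos, Il17a and Ccl5 were the highest ranked there, with 1 and 213, 2 and 409, and 1 and 186 UMIs; markers called 8 Keap1 cKO cells of this cluster and 0 control cells T cells. In red blood cells, taken as a measure of free RNA, S100a8, with 3 and 123 UMIs, stood at 6.02 (4.44 to 8.32), S100a9 at 5.53, Cd74 at 1.79, Gsn at −3.92, Krt15 at −2.29 and Retnla at −1.83.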

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

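The alternatives by cluster, those without cluster 14, those without erythrocytes, the gene list values with keratinocytes called by markers, those with cells of cluster 16 added, the one without dendritic cells in cluster 8, and those without Fth1 and Ftl1 were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. Of 255 alternatives of list medians, 239 kept their sign, and of 186 alternatives of single genes, 183 did. The 12 highest and 12 lowest genes were chosen for 1 direction across clusters, so their signs were likely to hold. Sizes moved more often. Among alternatives of shares, Keap1 and gene lists, 194 stayed inside the counting interval, 90 moved outside it and 6 reversed. Among the remaining results, mostly single genes, 131 stayed, 127 moved and 1 reversed. Only main values with a clear direction were counted as reversed. Epithelial cells were shallower in the Keap1 cKO library when pooled (median 5072.5 against 17667 UMIs) and in cluster 10 (809 against 1178), but deeper in clusters 4 (26254 against 20487), 9 (2456.5 against 1441.5), 13 (43123 against 28122), 14 (27848 against 3547.5) and 15 (35859 against 20225). A limit of 10% mitochondrial UMIs removed no cell. Where a value below differs from its value in the report, the cause was not tested.

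The epithelial share was 31.9% in the control library and 16.03% in the Keap1 cKO library without cells under 1000 UMIs. In the same order it was 32.3% and 16.9% with keratinocytes called by fixed markers, and 37.0% and 18.7% without erythrocytes. With keratinocytes called by markers, the medians were 1.08 for S phase, −0.21 for G2/M and 1.08 for antigen presentation. With the keratinocytes of cluster 16 added, S phase was at 1.17 and G2/M at −0.24. In myeloid cluster 2, G2/M reversed, to 1.23, with the dendritic cells and macrophages of cluster 16 added.

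With the mean over cells, the Keap1 log2 ratio was −1.14. The NRF2 lists together were at 0.70, with glutathione synthesis at 1.84, NADPH supply at 0.78, thioredoxin at 0.91, heme and iron at 0.74, and efflux at −0.051. Other list medians were 0.22 for the proteasome, 0.012 for esophageal differentiation, −0.29 for G2/M, 0.30 for the integrated stress response, −0.042 for heat shock, 0.55 for NF-kB, 0.13 for interferon, 0.42 for antigen presentation, −0.44 for Notch and 0.53 for lipid synthesis. The fibroblast matrix list reversed, to −0.17.

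With equal weights for clusters 4, 9, 10 and 13, and without clusters 14 and 15, Keap1 was at −1.11 and the NRF2 lists together at 0.34. Glutathione S-transferases were at 0.28, NADPH supply at 0.40 and thioredoxin at 0.60, and the detoxification list reversed, to −0.17. Esophageal differentiation reversed, to −0.43. The proteasome was at 0.19, the cornified envelope at 1.69, stress keratins at 4.02, S phase at 1.80, G2/M at 1.93 with its sign turned from −0.07, the integrated stress response at 0.23, antigen presentation at 0.58, Notch at −0.54, glycolysis at −0.081 and lipid synthesis at 0.45.

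In cluster 4 alone, Keap1 was at −0.40, the NRF2 lists at 0.80, basal identity at −0.60, esophageal differentiation at 0.026, stress keratins at 6.00, S phase at 2.43 and G2/M at 2.98. In cluster 9 alone, Keap1 was at −2.14, the NRF2 lists at 1.14, basal identity at −1.28, the cornified envelope at 1.78 and stress keratins at 2.77, and esophageal differentiation reversed, to −1.28. In cluster 13 alone, the NRF2 lists reversed, to −0.21, as did esophageal differentiation, to −0.46; basal identity was at −0.96, the cornified envelope at 2.06, stress keratins at 4.94, S phase at 0.65 and G2/M at 0.39.

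Without cluster 14, the NRF2 lists together were at 0.68, glutathione S-transferases at 0.79, detoxification at 0.45, NADPH supply at 1.04, thioredoxin at 0.94, the proteasome at 0.34, esophageal differentiation at 0.031, the cornified envelope at 3.57, stress keratins at 3.32, heat shock at 0.047, interferon at 0.18, the EGF family at −0.082 and glycolysis at 0.24.

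Median-of-ratios scaling put glutathione S-transferases at 0.71, and the NRF2 lists together at −0.16 in cluster 1 and −0.025 in cluster 8. Detoxification was at 0.59 with members of at least 100 UMIs. It was also at 0.59 when the minimum of 20 UMIs was loosened to 1 UMI in each library, where Notch was at 0.16. Without Scrublet-marked cells the fibroblast matrix list was at 0.63.

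At 50% of the thinning depth, G2/M UMIs were seen in 36.9% of control and 39.1% of Keap1 cKO epithelial cells, and S phase UMIs in 9.43% and 20.4%. At full depth the shares were 91.0% and 88.2% for G2/M, and 74.8% and 64.9% for S phase, in cells of unequal depth. The median share of NRF2 UMIs per epithelial cell was 2.38% in the control and 2.07% in the Keap1 cKO library over totals without mitochondrial and ribosomal protein genes, and 1.18% and 1.25% without Fth1 and Ftl1.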

Other observations

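The tests of cluster mix, of NRF2 genes in the remaining cells of cluster 4, of the cell cycle lists over clusters 4, 15 and 16, of the interferon genes of cluster 2 by marker type, of the antigen genes of cluster 8 without dendritic cells, of the ratio of clusters 3 and 2, and of free RNA behind the stress genes of cluster 4 were chosen after their results were seen. Outside the epithelium, several fixed lists moved in 1 direction in some cell types and not in others. Interferon response genes had median log2 ratios of 0.73 (0.44 to 0.88; percentile 99.99) in fibroblast cluster 1 and 0.86 (0.33 to 1.02; percentile 100) in myeloid cluster 2, but −0.72 (−0.95 to 0.19; percentile 0.110) in T cell cluster 3 and −0.33 (−0.59 to −0.07; percentile 0.770) in endothelial cluster 8. Within cluster 2 the interferon median was 0.80 (0.48 to 1.36) in cells called dendritic or Langerhans by markers, 103 of 169 control and 282 of 356 Keap1 cKO cells, and 0.077 (−0.34 to 0.43) in the 60 and 58 called macrophages. The dendritic markers include Cd74 and the class II genes H2-Aa and H2-Ab1. The 10 leading genes of cluster 2 held the macrophage markers Mrc1, C1qa and C1qb and no dendritic marker. This split therefore cannot tell a difference of cell type from one of class II level. Antigen presentation genes were lower in endothelial cluster 8 of the Keap1 cKO library, at −0.88 (−1.03 to −0.71), with 11 of 15 members at least 1.5-fold lower and none higher. Markers called 3 of its 53 control cells and 4 of its 203 Keap1 cKO cells dendritic or Langerhans, and without them the median was −1.21 (−1.37 to −0.97). G2/M genes stood at −1.36 (−1.62 to −0.90) in myeloid cluster 2, but the direction rested on where cycling cells were placed. Markers called 1 of 24 control cells and 11 of 48 Keap1 cKO cells of cluster 16 dendritic or Langerhans, and with those cells added the median turned to 1.23.

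Heat shock and immediate early genes, which dissociation induces, were lower in fibroblast cluster 1, at −0.53 (−0.63 to −0.48), in fibroblast cluster 5, at −0.65 (−0.84 to −0.51), and in endothelial cluster 8, at −0.55 (−0.65 to −0.36), while they stood at 0.21 in epithelial cells. Il22, a cytokine that acts on epithelia, was chosen after its values were seen. It had 0 control UMIs in both T cell clusters, with 98 UMIs in cluster 3 and 51 in cluster 11 of the Keap1 cKO library, at least 3.25-fold and 5.01-fold higher. Glycolysis genes stood at −0.41 (−0.52 to −0.23) in cluster 3, with 5 of 15 members at least 1.5-fold lower and 1 higher.

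The first pattern weighed is the higher level of NRF2 genes in the summed Keap1 cKO epithelial cells. A different mix of clusters as the whole cause is argued against by the medians inside clusters 4 and 9, of which the smaller was 0.80, above the random lists. Clusters 10 and 13 went the other way, at −0.60 and −0.21, so the summed value still depends on how the clusters are mixed. Free RNA is argued against because the median higher member reached only 0.982% as many UMIs per red cell as per epithelial cell. The quartiles over the 38 higher members were 0.382% and 1.65%. A candidate explanation is that part of the Keap1 cKO cells carry the difference: with cells ranked on every other NRF2 member, the remaining members had a median of 2.84 in the 14 cells of cluster 4 above the control 95th percentile and 0.028 (−0.070 to 0.24) in the other 79. The 14 cells had a median of 10113.5 UMIs and the other cells 27107, and Keap1 stood at 50.4 CPM (17 UMIs) and 58.9 CPM (134 UMIs), so its UMIs do not separate them. In cluster 9 the ranking members placed 60 Keap1 cKO cells above the control 95th percentile and 80 at or below it. The corresponding value in those 80 cells was 0.68 (0.48 to 0.90), against 1.85 in all cells. On all NRF2 members 72 of the 140 cells lay above, so the 80 still held cells of the upper range. This split therefore cannot decide and leaves the question open in cluster 9. The genotype itself stays untested with 1 library each.

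The second pattern is the higher level of S and G2/M genes in cluster 4 of the Keap1 cKO library. Cycling cells could have been placed in clusters 15 and 16 in the control library and left in cluster 4 in the other. For G2/M genes the values go with this: the median of 2.98 in cluster 4 came to 0.41 (0.36 to 0.53) over clusters 4 and 15 together, and to 0.22 (0.15 to 0.32) with the keratinocytes of cluster 16, which were 16 control cells and 0 Keap1 cKO cells. For S phase genes such placement accounts for a part and is argued against as the whole cause, since the median was 2.43 in cluster 4, 2.23 (2.04 to 2.43) over clusters 4 and 15, and 1.77 (1.69 to 1.98) with the keratinocytes of cluster 16. Free RNA was low for these genes in the Keap1 cKO library: Dut had 0.0417 UMIs per red cell against 1.42 per epithelial cell, and Rrm2 and Exo1 had 0 UMIs in 120 red cells. At matched depths the share of epithelial cells with an S phase UMI was higher in the Keap1 cKO library, 26.5% against 19.2% at 700 UMIs, without the cells of cluster 16. Whether more cells were in S phase stays open, because such UMIs were also seen in 87.0% of control fibroblasts of cluster 1 at full depth and 1 library stands for each genotype.

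The third pattern is the higher share of T cell, myeloid and endothelial cells in the Keap1 cKO library. A lower yield of epithelial cells and fibroblasts would raise all other cells alike. The ratio of cluster 3 to cluster 2 cells was 3.04 (2.16 to 4.31) times as high in the Keap1 cKO library. For cluster 3 this argues against that yield as the whole cause. Among cells other than epithelial cells and fibroblasts, cluster 3 made up 9.47% of the control library and 24.7% of the Keap1 cKO library, cluster 2 made up 27.1% and 23.3%, and red blood cells 28.6% and 7.84%. Of the same cells, cluster 8 made up 8.51% and 13.3% and cluster 12 made up 5.46% and 11.6%. T cell cluster 11 made up 9.31% (7.15 to 11.9) and 10.6% (9.15 to 12.3), so its share does not speak against the yield. Residual blood and the dissociation of each tissue stay open as sources of these differences.

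A hypothesis was that the stress keratins and alarm genes of cluster 4 are carried by the cells with a high NRF2 share. As the whole source, high-share cells are argued against by the 59 Keap1 cKO cells at or below the control median NRF2 share. In these the list still had a median log2 ratio of 3.54 (3.22 to 3.93), and 58 Keap1 cKO cells lay within 20% of that threshold. The median was 6.00 in all cells of cluster 4, over 13 members against 12 in the 59 cells. A part of the difference may have gone with the cells of higher share, which were not measured on their own. Red cells had 3.51 (2.89 to 5.27) for the same list, so the ratio of 3.54 alone does not decide. Free RNA as the source of the 3.54 is argued against because the median higher member had only 1.63% as many UMIs per red cell as per cell of these 59. The quartiles over the 10 higher members were 1.26% and 2.83%. A further hypothesis was that the low Ndufa4l2 and Egln3 reflect a lower hypoxia response. Without these genes, the 18 measured members of a hypoxia list had a median of −0.30 (−0.46 to −0.14) at percentile 2.73, just inside the central 95% of random lists. The median was −0.46 at percentile 0.40 in cluster 4, −0.19 at percentile 15.995 in cluster 13 and −0.46 at percentile 22.86 in cluster 9, which leaves this undecided.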
